A study of Streptomyces clavuligerus with 6 samples.

How the data were processed

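The samples were cultures of 1 Streptomyces clavuligerus strain, labelled oppA2::acc, an oppA2 mutant that the series text calls deleted. They were grown in SA (starch-asparagine) medium and collected at 22.5, 46.5 and 60 h, with 2 biological replicates per time and 1 array each, 6 arrays in all. Per the labels, samples were stabilized with a bacterial RNA protection reagent, disrupted with lysozyme and silica beads, extracted with phenol and chloroform, purified on columns and treated with DNase. RNA with an integrity value above 7 was used. Total RNA was reverse transcribed from random primers with Cy3, and genomic DNA of the parent strain, from a stationary-phase culture, was labelled from random primers with Cy5 as the reference on every array. RNA of the parent strain was not analysed here.

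The custom Agilent array had 15744 spots, of which 15208 were for genes or tiles and 536 were controls. Its 14908 probes comprised 9349 gene-designed probes, 2310 tiling probes that carry a gene name and 3249 tiling probes without one, which entered no gene test. A gene name was a symbol for 871 genes and a locus tag for 6664, 1051 genes had more than 1 probe, and 30 probes were printed 11 times each. Positions are the array's own design coordinates; the genome build behind them is not given in the sources used here.

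Mean signal and median local background intensities per spot were deposited as scanned, on a linear scale, made with Agilent Feature Extraction 9.5.1.1 in its 2-channel CGH protocol per the file headers. Processed signal intensities were background-subtracted, detrended and linearly dye-normalized by the same program, per the file headers. Per the file headers the flags for each spot (well above background, saturated, not uniform, population outlier) are other values, 0 or 1. The deposited value table holds log2 ratios of Cy3 to Cy5 up to a shift and a stretch per array. The slopes of its columns on the log2 ratios of the best-matching scanner file ran from 1.02 to 1.28. For this table the authors named limma without settings or a version, and control spots and 1819 further gene spots are empty in it. Only 2 of the 6 columns of this table correlated best with the scanner file of the sample they are named for, so the table was used as an alternative and not for the reported values.

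Both channels were background-corrected by normexp with an offset of 50 on the mean signal and median background. Log2 ratios of Cy3 to Cy5 were taken and each array was centred on its median over gene probes. Control spots were left out and spots flagged as outliers were set to missing, from 18 to 64 per array. Spots of a probe and then probes of a gene were averaged. Genes well above background in Cy3 on at least 2 of 6 arrays were tested, which left out 2 genes. Loess within each array was kept as an alternative, because against genomic DNA a probe's brightness follows its RNA level and a curve fitted to brightness removes part of the RNA signal.

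Median Cy5 signals of gene spots were 3121 and 4646 at 22.5 h, 3890 and 3973 at 46.5 h, and 4801 and 4598 at 60 h (replicates 1 and 2). At most 9 spots per array were saturated in Cy3 and 0 in Cy5. The slide was read from the barcode in the scanner file names: replicate 1 of 22.5 h and 46.5 h was on slide 1 and the other 4 arrays were on slide 2, so slide 1 held no 60 h array.

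Times were compared in 1 limma fit to all 6 arrays with time as a factor of 3 levels and a moderated variance with an intensity trend. There were 3 residual degrees of freedom and a prior of 4.88, and the median standard error of a log2 change was 0.288. Changes at any time were tested by the moderated F-test. Calls were Benjamini-Hochberg adjusted p under 0.05, from 2-sided tests. Values after ± are standard errors of the fit unless said otherwise. The 2 replicates per time limit what p-values can show, since the spread of a gene rests on few arrays and on the prior. On simulated data with the same number of arrays, 200 of 7477 genes were changed. Of changes of 1 (log2) the tests recovered 18%, 25% and 21% in the 3 comparisons, and of changes of 2 they recovered 96%, 96% and 98%, with 7, 11 and 9 false calls. The simulated noise was normal and independent between genes and arrays, without slide or replicate effects, a brightness trend or a signal floor. These false calls therefore do not give the error rate of the calls in the real data.

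Gene lists were written from gene symbols and locus tags, since the files have no product descriptions, and functions stated for genes are background knowledge of the symbols. Of 39 lists, 10 were made from the gene names of the array before any test; the others, the tests and the rule for naming genes were written before the data were examined. Lists with at least 4 tested genes, 37 of them, were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data. A list is called shifted when its adjusted p was under 0.05 with the preset correlation. Members were counted with p adjusted over all genes and over the list alone.

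Genes were named by rule: oppA2, ccaR and claR; in each comparison the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the times, with genes known only by a locus tag given as a count; and up to 4 members of each tested list with the smallest p, of which a part is printed. Genes named outside the rule are said to be named after their values were seen.

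Alternatives were loess within each array, quantile and scale normalization of ratios between arrays, and Cy3 alone with quantile normalization. Further ones were no background correction, Agilent's processed signals, the deposited value table as labelled, no filter, a filter on all 6 arrays, the brightest probe of a gene, outlier spots kept and no intensity trend. The model was varied with a replicate block, with slide as a fixed term, with only the 2 times compared, by leaving out each array in turn and with an estimated correlation for lists. Gene-designed probes alone and slide 2 alone were added after seeing the data. The value table was run for counts, lists and oppA2, not for single genes.

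The computations used R 4.3.3 with limma 3.58.1, statmod 1.5.0, jsonlite 2.0.0 and the data.table package (version 1.17.8), and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. Random lists of like brightness were drawn 10000 times with a fixed seed.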

Results

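RNA levels were measured in an oppA2 mutant of Streptomyces clavuligerus at 22.5, 46.5 and 60 h of culture in a starch-asparagine medium. Each time had 2 biological replicates with 1 array each, 6 arrays in all. S. clavuligerus is a soil bacterium that makes the β-lactamase inhibitor clavulanic acid and the β-lactam antibiotic cephamycin C. Its oppA2 gene lies in the clavulanic acid cluster and codes for an oligopeptide-binding protein. The Cy3 channel of each array held the mutant's RNA and the Cy5 channel held genomic DNA of the parent strain, so the log2 ratio of Cy3 to Cy5 read the RNA of a gene against the same DNA reference on every array. RNA of the parent strain was not analysed here. Every comparison is therefore between times of the mutant, and none shows what the loss of oppA2 does. The comparisons address which genes change between culture times in this strain.

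The array named 7535 genes, 5926 on the chromosome and 1609 on the plasmid pSCL4, and 7533 were tested. The median Cy3 signal of gene spots was 608 and 620 at 22.5 h, 720 and 1144 at 46.5 h, and 372 and 313 at 60 h (replicates 1 and 2). Negative control spots had Cy3 medians from 62.3 to 91.3, and at least 99.8% of gene spots on each array were well above background in Cy3. Across genes, the log2 ratios of the 2 replicates correlated at 0.978 at 22.5 h, 0.943 at 46.5 h and 0.988 at 60 h, where genes are not independent replicates. The 22.5 h and 46.5 h pairs were each divided between 2 slides, and both 60 h arrays were on slide 2. The number of arrays limits the precision of every value.

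The 3 probes designed for oppA2 read low at every time. Their mean log2 ratio was -3.02 and -2.73 at 22.5 h, -2.90 and -3.03 at 46.5 h, and -2.23 and -2.02 at 60 h, between percentiles 10.9 and 16.9 of all genes. Their Cy3 signals ran from 75.2 to 199. On 5 arrays they lay under the brightest negative control, and at 46.5 h replicate 2 they were 124 to 199, against a negative control median of 91.3 and a highest control of 165. The gene also carried 21 tiling probes, whose log2 ratios ran from -2.82 to 3.83, with between 5 and 10 of them above 0 on each array. Over all 24 probes, which span positions 4843565 to 4845189 of the chromosome in the array's own coordinates, the mean log2 ratio was -0.79 ± 0.24 (SD over 6 arrays). The value was -0.24 with loess within each array, -1.62 with Agilent's processed signals and -0.20 in the authors' value table. The columns of that table were not centred and had medians from 0.24 to 0.60, so its value is on another zero. The labels do not say which part of the gene was replaced, and without RNA of an intact strain these values test no loss of its RNA.

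**Figure D1:**
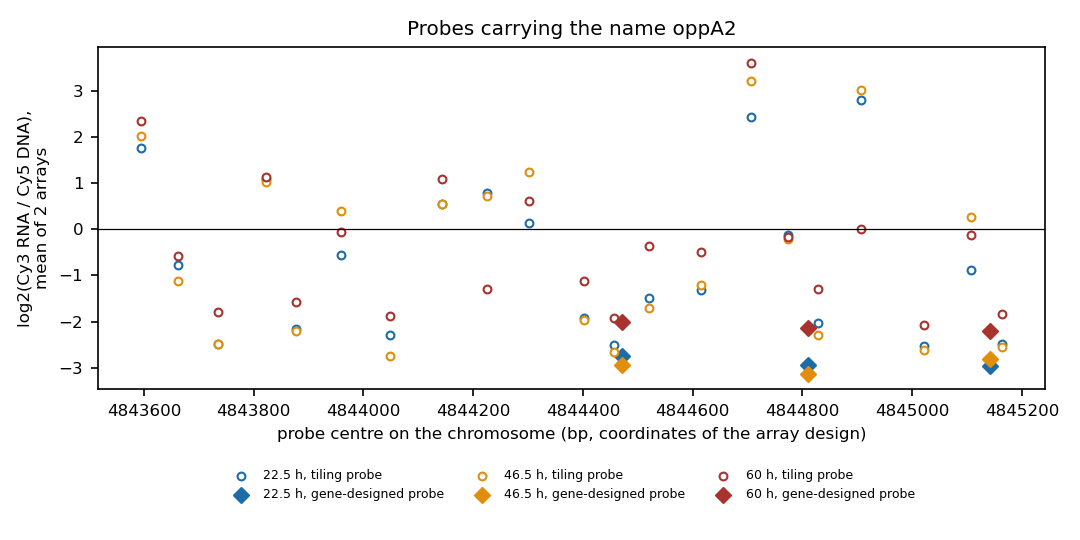
Log2 ratio of Cy3 RNA to Cy5 genomic DNA of the 24 oppA2 probes (mean of 2 arrays, a colour per time) by position on the chromosome in bp, with filled diamonds for the 3 gene-designed probes and open circles for the 21 tiling probes. The mean of the gene-designed probes was between -3.03 and -2.02 on single arrays, and single tiling probes ranged from -2.82 to 3.83.

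Between 22.5 h and 46.5 h the largest named rises included siderophore synthesis genes, gunC and arcB_1. The siderophore synthesis genes sidD, alcA and sidE rose 62.7-fold (log2 change 5.97 ± 0.53 SE, limma adjusted p = 0.000739), 60.8-fold (5.93 ± 0.49) and 15.7-fold (3.97 ± 0.33), with n = 2 arrays per time here and below. hmuO, a haem oxygenase, and hmuV, the ATPase of a haemin transporter, rose by 2.46 ± 0.30 and 2.44 ± 0.38, and these are both tested members of the iron uptake list, which was too small for a list test. gunC, of the secreted hydrolase list, rose 56.3-fold (5.82 ± 0.46, adjusted p = 0.000639), arcB_1, an ornithine carbamoyltransferase gene, rose 17.9-fold (4.16 ± 0.34), and glnA1, a glutamine synthetase gene, rose 4.10-fold (2.04 ± 0.40, adjusted p = 0.0203). The nitrogen assimilation list had 1 rise of 5 genes and was not shifted (median 2.035, camera adjusted p = 0.144). Its median differed between slides, 0.30 on slide 1 and 2.74 on slide 2. No gene of the β-lactam clusters passed the test (1 of the clavulanic acid cluster rose with Cy3 alone), and the cluster medians were between 2.99 and 4.30 (log2 ratio) on all 4 arrays of these times.

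Of 10 secreted hydrolase genes, 3 rose and none fell, namely gunC, sprE (2.04 ± 0.32) and sprT (1.89 ± 0.27), and 4 rose when adjusted over the list alone; the list did not pass its own test (camera adjusted p = 0.0694, but 0.0458 with Cy3 alone). fabF on pSCL4, a ketoacyl-carrier-protein synthase gene, rose by 3.35 ± 0.29 and was the 1 member of 14 fatty acid synthesis genes to pass. Among 24 NADH dehydrogenase genes, nuoJ1 (1.31 ± 0.27) and nuoL1 (1.39 ± 0.32) rose and none fell, while 8 rose and 7 fell when adjusted over the list alone. The list was not shifted (adjusted p = 0.168), though it was with Cy3 alone (median 1.08, 11 rises, adjusted p = 0.0139). Of the 20 largest changes under any name, 17 were genes with a locus tag only.

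The largest falls among genes with a symbol were insA (-2.69 ± 0.22), ansP (-2.64 ± 0.40), cdo2 (-2.63 ± 0.30), yqjG (-2.51 ± 0.38) and aphD (-2.51 ± 0.40, adjusted p = 0.00781), then metX, paaR, whmD, pteH and atpA2, between -2.14 and -1.86. ansP codes for an asparagine permease, aphD for an aminoglycoside phosphotransferase, metX for a homoserine acetyltransferase and atpA2 for an ATP synthase alpha subunit. Of 23 amino acid synthesis genes 5 fell and none rose, namely leuC (-1.59 ± 0.33), asd1 (-1.36 ± 0.32), aroH2 (-1.35 ± 0.29), trpB (-1.09 ± 0.25) and trpA (-1.05 ± 0.25), and 9 fell when adjusted over the list alone; trpA was named after its value was seen. In the holomycin cluster, whose product is an antibiotic, SCLAV_5278 (-2.15 ± 0.26) and SCLAV_5274 (-1.68 ± 0.33) fell, 2 of 12 genes, or 3 adjusted over the list alone. Of 33 tRNA synthetase and translation factor genes 3 fell, among them cysS (-1.35 ± 0.31) and argS (-1.17 ± 0.28), and fusA1 rose (1.35 ± 0.30), with 4 falls and 1 rise adjusted over the list alone. Of 53 tRNA genes 3 fell, led by SCLAV_t025 (-2.59 ± 0.41), and 1 rose, as also when adjusted over the list alone. None of 40 ribosomal protein genes passed, nor did any when adjusted over the list alone, rplL being nearest (-1.20 ± 0.33, adjusted p = 0.0716).

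Against all other genes, 5 of 37 lists were shifted, all downwards, by limma's camera with a preset correlation, and 0 with an estimated correlation. Median log2 changes were -0.73 for amino acid synthesis (adjusted p = 0.00429), -0.58 for ribosomal proteins (9.01e-05), -0.53 for tRNA synthetases and translation factors (0.00828), -0.43 for the holomycin cluster (0.0191) and -0.41 for tRNA genes (0.0383). Each had adjusted p = 0.874 with an estimated correlation. With loess within each array, only the holomycin cluster of these 5 was shifted, and with quantile normalization the tRNA genes were not. The medians were -0.55, -0.47, -0.37, -0.22 and -0.16 on slide 1 and -0.90, -0.76, -0.64, -0.67 and -0.66 on slide 2, in the same order. The clavulanic acid cluster had 0 of 17 genes past the test (median 0.16, 0.25 on slide 1 and 0.11 on slide 2; shifted upwards with Cy3 alone, median 0.39, adjusted p = 0.0241). The cephamycin C cluster had 0 of 19 (median -0.25, -0.21 on slide 1 and -0.31 on slide 2), and adjusted over the list alone each cluster had 0. Their regulator genes ccaR, at positions 4881991 to 4882676, and claR, at 4852445 to 4853665, had log2 changes of -0.60 ± 0.28 (adjusted p = 0.236) and -0.50 ± 0.35 (0.409).

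In all, 560 of 7533 genes changed between 22.5 h and 46.5 h, 216 up and 344 down, and the median log2 change of all genes was -0.07. The count was 160 with loess within each array, 1198 with replicate number and 1357 with slide as a fixed term, 351 with the 2 times alone, and 2822 on slide 2 alone. Slide 2 held 1 array of 22.5 h and 1 of 46.5 h, so the spread in every test on it came from the 60 h pair alone, whose replicates differed least (SD of the difference 0.325, against 0.468 at 22.5 h and 0.736 at 46.5 h). It was 294, 287, 2350, 351 and 351 without 22.5 h replicate 1, 22.5 h replicate 2, 46.5 h replicate 1, 60 h replicate 1 and 60 h replicate 2, and 9 lists were shifted without 46.5 h replicate 1.

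Between 22.5 h and 60 h the RNA of both β-lactam clusters fell. In the clavulanic acid cluster (chromosome, 4839288 to 4862963), 16 of 17 genes fell, and the median log2 ratio of the cluster was 3.96 or higher on both 22.5 h arrays and 1.59 and 1.40 at 60 h. In the cephamycin C cluster next to it (4863447 to 4899336), 18 of 19 genes fell and the median went from 3.29 and 2.99 to 1.01 and 0.96. SCLAV_4215, named after its values were seen, lies within the range of cmcI and had nearly the same log2 ratios at 22.5 h (4.87 and 4.66, against 4.71 and 4.53) and at 60 h. The counts for this list may therefore hold 1 region 2 times. The 17 clavulanic acid genes leave out oppA2, which lies within that cluster's range. The mean log2 ratio of its 24 probes was -1.07 and -0.81 at 22.5 h and -0.78 and -0.40 at 60 h, so it was not lower at 60 h. The biosynthetic genes cefD (an epimerase), cmcJ and cmcI (methoxylation of cephamycin C) fell 13.5-fold (-3.75 ± 0.30, adjusted p = 0.000108), 12.1-fold (-3.59 ± 0.31) and 11.5-fold (-3.52 ± 0.27), and blp, in the same cluster, fell 17.9-fold (-4.16 ± 0.29). In the clavulanic acid cluster fd, a ferredoxin gene, fell by 3.22 ± 0.27, oppA1, the oligopeptide-binding paralogue of oppA2, by 2.68 ± 0.31, and the synthesis genes pah2 and ceaS2 by 2.67 ± 0.29 and 2.56 ± 0.30.

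The regulator gene claR fell 4.16-fold (-2.06 ± 0.35, adjusted p = 0.00257), and ccaR fell 3.21-fold (-1.68 ± 0.28, adjusted p = 0.00239) but its change was 0.06 with loess within each array. The members that did not fall, named after their values were seen, were SCLAV_4184 (0.22 ± 0.24), which directly follows oppA2 and had a log2 ratio between -2.32 and -1.88 on every array, and SCLAV_4217, at the far end of the cephamycin C list, which rose by 0.84 ± 0.27 (adjusted p = 0.034). This rise of SCLAV_4217 did not pass with loess or with quantile or scale normalization. Its log2 ratios were low, between -1.89 and -0.42, and dim genes rose as a group, so its rise is not shown to oppose the cluster's fall. A fall from a low ratio was seen in SCLAV_4209, named after its values were seen, from -1.37 and -1.21 to -3.51 and -3.22. Counts adjusted over the list alone were the same in both clusters. The clusters were shifted with median log2 changes of -2.08 (camera adjusted p = 5.69e-08) and -2.15 (5.12e-09), each with adjusted p = 0.565 with an estimated correlation. With loess the medians were -0.56 and -0.59, with 5 and 8 falls, and on slide 2 alone the cephamycin C median was -2.15 and both clusters were shifted.

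**Figure D2:**
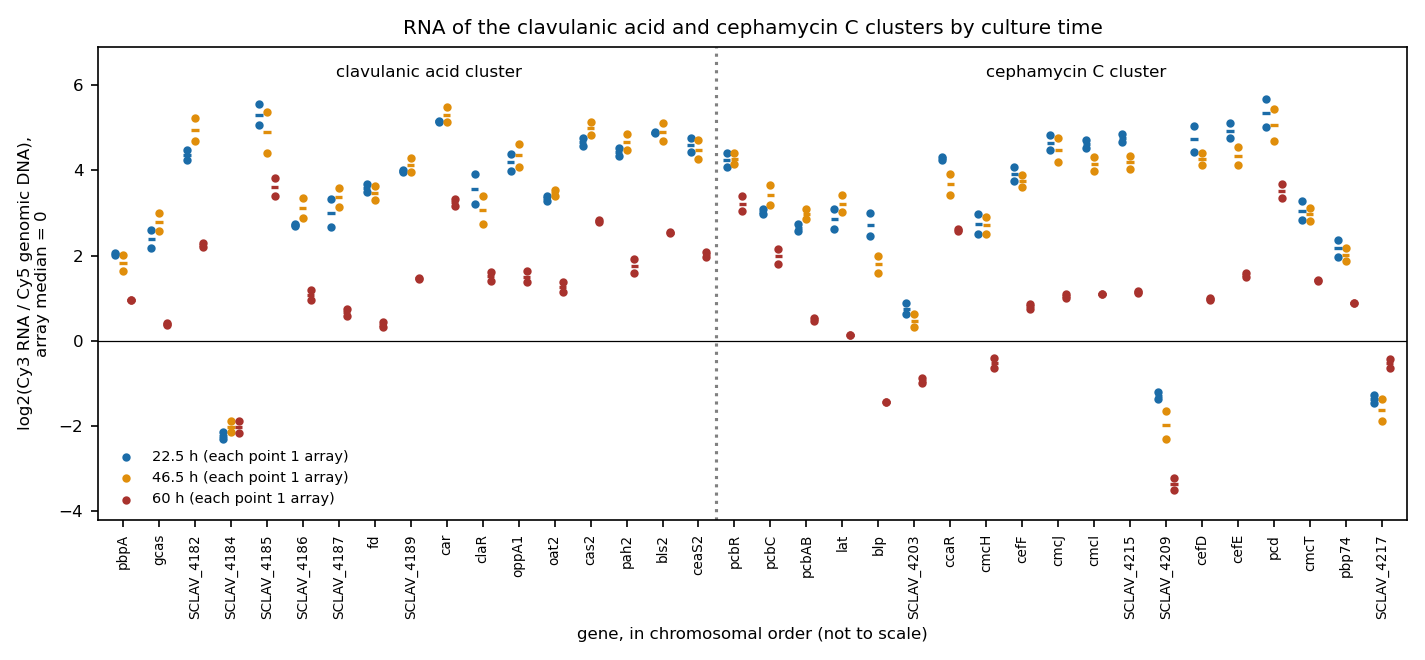
Log2 ratio of Cy3 RNA to Cy5 genomic DNA for each listed gene of the clavulanic acid and cephamycin C clusters (oppA2 left out) in chromosomal order, with points for single arrays and bars for the mean of 2 arrays per time. The cluster medians lay between 2.99 and 4.30 on the 22.5 h and 46.5 h arrays and between 0.96 and 1.59 on the 60 h arrays, a fall that loess within each array reduced to medians of -0.56 and -0.59 without turning it.

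Falls from 22.5 h to 60 h covered 32 of 40 ribosomal protein genes, and none rose (35 fell adjusted over the list alone), among them rplQ (-2.48 ± 0.26) and rplL (-2.44 ± 0.33). Of 33 tRNA synthetase and translation factor genes 22 fell, with hisS at -2.34 ± 0.30 and the elongation factor gene efp at -2.37 ± 0.30, and 1 rose (24 and 2 adjusted over the list alone). That rise was fusA1, an elongation factor G gene, 24.3-fold up (4.60 ± 0.30, adjusted p = 4.65e-05). In the cytochrome list 5 of 6 genes fell, with ccsA at -2.67 ± 0.32 and qcrC at -2.23 ± 0.29, and in the citric acid cycle list 5 of 6 fell, with sucC at -2.37 ± 0.27 and the citrate synthase gene gltA at -2.20 ± 0.32, while citA rose (1.32 ± 0.26). Of 12 chaperone and protease genes 5 fell, led by groES1 (-2.98 ± 0.31) and groEL1 (-2.78 ± 0.31), and of 24 NADH dehydrogenase genes 8 fell, with nuoI2 at -2.11 ± 0.27. Counts in these last 4 lists were the same adjusted over the list alone.

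These lists were shifted downwards, with median log2 changes of -1.61 for ribosomal proteins (camera adjusted p = 1.02e-10), -1.10 for tRNA synthetases and translation factors (1.20e-05), -2.18 for cytochromes (0.00432), -1.83 for the citric acid cycle (0.0303), -0.75 for chaperones (0.0204, but median 0.07 with loess) and -0.60 for NADH dehydrogenase (0.00184, but median 0.20 with loess and 0.25 with Cy3 alone). With an estimated correlation the adjusted p was 0.565 for ribosomal proteins, cytochromes and the citric acid cycle, 0.607 for tRNA synthetases and translation factors, and 0.673 for chaperones and NADH dehydrogenase. On slide 2 the medians were -1.43, -1.02, -1.93, -1.64, -0.67 and -0.43, in the same order. With loess none of the 6 lists was shifted, and the medians of the first 3 were 0.00, -0.02 and -0.03. The falls with loess were 0 of 40 ribosomal protein, 6 of 33 tRNA synthetase and translation factor, 1 of 6 cytochrome, 0 of 6 citric acid cycle, 0 of 12 chaperone and 3 of 24 NADH dehydrogenase genes. Genes of like brightness had medians of -0.55, -0.25, -0.33, -0.48, -0.44 and -0.36, and 11, 72, 63, 317, 2800 and 2672 of 10000 random lists of like brightness had a median as low. Chaperones and the citric acid cycle were not shifted with quantile or scale normalization or Cy3 alone either, nor were chaperones with Agilent's processed signals (0.0592), nor was NADH dehydrogenase with Cy3 alone.

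In 6 further lists that were shifted downwards, the share of members that fell ranged widely. Among amino acid synthesis genes 17 of 23 fell, with ilvH, an acetolactate synthase gene, down 17.3-fold (-4.11 ± 0.29) and trpB at -2.67 ± 0.25, and leu, outside the list, was the largest named fall, 32.1-fold (SE 0.27 on the log2 scale, adjusted p = 3.15e-05). Of 22 nucleotide synthesis genes 16 fell (18 adjusted over the list alone), with the purine genes purN and purH down 16.3-fold (-4.03 ± 0.32) and 13.2-fold (-3.73 ± 0.34) and the ribonucleotide reductase gene nrdL at -3.43 ± 0.25, while guaB1, named after its value was seen, rose by 1.85 ± 0.26. Of 14 arginine and urea genes 6 fell, led by argB (-3.60 ± 0.32). Of 19 cell division and peptidoglycan genes 15 fell, among them mraY1 (-2.81 ± 0.24) and murE (-2.73 ± 0.34), and mreB1, named after its value was seen, rose by 0.94 ± 0.23. No gene of this list rose with loess or scale normalization, and 1 rose with quantile normalization. All 6 ectoine synthesis genes fell, with ectA1 at -2.45 ± 0.30 and ectB1 at -2.33 ± 0.24; ectoine is a solute that protects against osmotic stress. Of 17 moe genes on pSCL4 5 fell and 1 rose. aphD fell by 3.75 ± 0.40. Unless given, counts adjusted over the list alone were the same.

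The medians were -1.94 for amino acid synthesis (camera adjusted p = 5.58e-07), -1.27 for nucleotide synthesis (1.91e-06), -0.09 for arginine and urea metabolism (0.0367), -1.08 for cell division and peptidoglycan (2.74e-05), -2.02 for ectoine synthesis (6.57e-04) and -0.66 for the moe genes (0.00868). With an estimated correlation the adjusted p was 0.635 for arginine and urea metabolism and 0.565 for the other 5. Slide 2 gave medians of -2.02, -1.27, -0.36, -0.97, -2.14 and -0.55, and none of loess, quantile and scale normalization and Cy3 alone turned a direction, but loess reduced most of the falls. With loess the medians and falls were -0.65 and 8 for amino acid synthesis, -0.20 and 8 for nucleotide synthesis, -0.08 and 6 for cell division and peptidoglycan, -0.75 and 3 for ectoine synthesis and -0.45 and 3 for the moe genes. The arginine list was not shifted with quantile or scale normalization or with a replicate block (adjusted p = 0.0670), and the moe genes were not with quantile or scale normalization or Cy3 alone. With a replicate block 4 arginine genes also rose, and 11 moe genes fell. Random lists of like brightness with a median as low numbered 0, 51, 1787, 132, 2 and 1656 of 10000, in the order of the lists.

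The largest named rises at 60 h against 22.5 h were accD, 2 bkd genes and mmsB1. accD, an acyl-CoA carboxylase subunit gene, rose 51.7-fold (5.69 ± 0.30, adjusted p = 2.99e-05), and bkdA1 and bkdB1, subunits of the branched-chain keto acid dehydrogenase, rose by 5.36 ± 0.33 and 5.22 ± 0.31 (log2). mmsB1 of valine breakdown rose 27.7-fold (4.79 ± 0.32), gabT, an aminobutyrate aminotransferase gene, 23.7-fold (4.57 ± 0.40), and paaA and paaZ of phenylacetate breakdown 15.1-fold (3.91 ± 0.24) and 10.5-fold (3.40 ± 0.28). sprE rose 22.4-fold (4.49 ± 0.32) and dnaQ1, for a DNA polymerase III epsilon subunit, 10.6-fold (3.40 ± 0.30). Of the 20 largest changes under any name, 19 were genes with a locus tag only.

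In the branched-chain keto acid dehydrogenase list 3 of 5 genes rose, bkdC among them (2.63 ± 0.36), and 4 adjusted over the list alone. All 6 inositol genes rose, with iolJ at 2.61 ± 0.28 and iolA at 2.51 ± 0.31, and 4 of 5 glycerol genes rose, with the kinase gene glpK at 2.78 ± 0.24 and the facilitator gene glpF1 at 2.58 ± 0.25, as when adjusted over the list alone. Of 15 sta genes on pSCL4 7 rose, with staN at 0.84 ± 0.23, and 12 adjusted over the list alone. Of these genes 0 rose with loess (median 0.24) and with Cy3 alone (0.39), and 13 with a replicate block. The sta median of 0.78 compares with 0.56 for genes of like brightness, and 873 of 10000 random lists of like brightness had a median as high. For the branched-chain keto acid dehydrogenase, inositol and glycerol lists 2, 11 and 85 random lists were as high. Of all 1609 pSCL4 genes 426 rose and 230 fell, or 398 and 224 adjusted over the list alone. The pSCL4 counts were 273 and 171 with loess, 311 and 284 with quantile and 320 and 309 with scale normalization, 321 and 269 with Cy3 alone, and 582 and 271 with a replicate block. These lists were shifted upwards with medians of 2.63 (camera adjusted p = 0.0169), 1.96 (0.00344), 1.54 (0.0422), 0.78 (0.0129) and 0.50 (0.0434), and 2.67, 2.08, 1.54, 0.61 and 0.42 on slide 2. With an estimated correlation the adjusted p was 0.673 for the sta genes and 0.565 for the other 4. With loess only the first 2 of these 5 lists were shifted, the sta genes were not with Cy3 alone, and the pSCL4 list was not with any of the 4 other scalings, where its median was between 0.15 and 0.25. The glycerol list was not shifted with a replicate block (adjusted p = 0.0581) or Agilent's processed signals (0.0503), nor was the pSCL4 list with processed signals (0.172) or slide as a fixed term (0.101). On slide 2 alone the glycerol, pSCL4 and sta lists were not shifted.

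Some lists had many changed genes but were not shifted as a whole, though 2 of them were with other scalings. Of 24 sporulation and development genes 11 rose, with the regulator genes wblA (1.89 ± 0.27) and bldM (1.79 ± 0.35), and 2 fell. The median was 0.78 (camera adjusted p = 0.197, but 0.0447 with scale normalization and 0.0221 with Cy3 alone). Of 10 secreted hydrolase genes 6 rose, with lamA at 2.57 ± 0.26, and amy, named after its value was seen, fell by 2.02 ± 0.45, or 6 and 2 adjusted over the list alone. The median was 1.66 (0.0966, but 0.0409 with quantile and 0.0374 with scale normalization and 0.0343 with Cy3 alone). Of 4 histidine use genes 3 rose, with the urocanate hydratase gene hutU at 3.17 ± 0.35, and 1 fell (median 2.37, 0.226). In the oxidative stress list the catalase gene katA rose (2.34 ± 0.27) and 4 of 8 genes fell, led by tpx (-3.21 ± 0.42) and ahpC (-2.96 ± 0.25). The list had a median of -1.19 that was 0.02 with loess (0.12). Of 7 glycolysis genes 4 fell, with pgk at -3.38 ± 0.25 and tpiA at -3.19 ± 0.31, and 2 rose (median -1.10, 0.236), or 3 rises adjusted over the list alone. With loess 3 glycolysis genes rose and 2 fell (median -0.28). Of 13 genes of RNA polymerase, sigma and transcription factors 5 fell, led by rpoA (-2.27 ± 0.30), and 2 rose, but 5 rose and 5 fell with a replicate block, and 6 and 5 with slide as a fixed term. The list had a median of -0.39 that was between 0.09 and 0.42 with loess, quantile or scale normalization or Cy3 alone (0.276).

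In all, 3521 of 7533 genes changed between 22.5 h and 60 h, 1837 up and 1684 down, and 2669 by over 2-fold, 1254 up and 1415 down. Of the 37 lists, 19 were shifted, 5 up and 14 down, and 0 with an estimated correlation. The median log2 change of all genes was 0.28, and 0.18 with loess, 0.14 with quantile and 0.10 with scale normalization of the ratios and 0.12 with Cy3 alone. Changes followed brightness: of 10 groups of genes by Cy3 brightness the dimmest had a median change of 0.73 and the brightest -0.65. The dimmest group had 363 rises and 1 fall, and the brightest 130 rises and 342 falls. The count was 2151 with loess, 3864 with slide as a fixed term, 4741 on slide 2 alone, and 2100, 1700 and 1845 without 22.5 h replicate 1, 60 h replicate 1 and 60 h replicate 2.

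**Figure D3:**
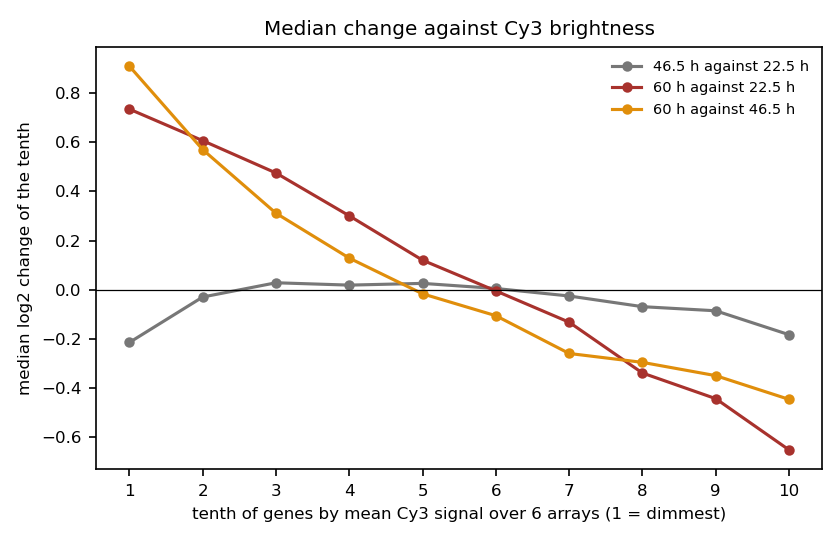
Median log2 change of genes in 10 groups of equal size by mean Cy3 brightness, for the 3 comparisons. At 60 h against 22.5 h the medians ran from 0.73 in the dimmest to -0.65 in the brightest group, and at 46.5 h against 22.5 h they lay between -0.21 and 0.03. At 60 h against 46.5 h they ran from 0.91 to -0.45.

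Between 46.5 h and 60 h arcB_1, alcA, sidD and gunC had the largest named falls, and both β-lactam clusters fell. arcB_1 fell 26.2-fold (-4.71 ± 0.34, adjusted p = 0.000159), alcA by 4.39 ± 0.49 (log2), sidD 19.8-fold (-4.31 ± 0.53) and gunC 17.3-fold (-4.11 ± 0.46). purN (-3.95 ± 0.32), leu (-3.83 ± 0.27), purH (-3.56 ± 0.34), cmcJ (-3.42 ± 0.31), alaT (-3.41 ± 0.29) and argB (-3.33 ± 0.32) complete the 10 largest named falls. In the clavulanic acid cluster 16 of 17 genes fell, with fd at -3.10 ± 0.27 and pah2 at -2.90 ± 0.29, and in the cephamycin C cluster 18 of 19, with blp at -3.23 ± 0.29 and cmcI at -3.06 ± 0.27, as when adjusted over the list alone. SCLAV_4184 had a change of 0.00 ± 0.24 and SCLAV_4217 rose 2.14-fold (SE 0.27 on the log2 scale), both named after their values were seen. Both had negative log2 ratios on every array, and dim genes rose as a group here too. claR fell by 1.56 ± 0.35 (adjusted p = 0.0119), and ccaR by 1.08 ± 0.28 (adjusted p = 0.0204), though its change was 0.20 with loess.

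The largest named rises were in bkd genes and accD. bkdB1 and bkdA1 rose 56.1-fold (5.81 ± 0.31, adjusted p = 6.93e-05) and 49.4-fold (5.63 ± 0.33), accD 35.8-fold (5.16 ± 0.30), paaA 22.2-fold (4.47 ± 0.24), gabT 16.4-fold (4.04 ± 0.40) and mmsB1 10.9-fold (3.45 ± 0.32), followed by sgiA, fusA1, dnaQ1 and paaZ between 3.33 and 3.18. All 5 branched-chain keto acid dehydrogenase genes rose, with bkdC at 2.94 ± 0.36, and all 6 inositol genes, with iolE up 7.99-fold (SE 0.32 on the log2 scale) and iolJ at 2.77 ± 0.28, as when adjusted over the list alone. Of 24 sporulation and development genes 9 rose, among them ssgB (2.11 ± 0.35) and wblA (2.04 ± 0.27), and 1 fell, as when adjusted over the list alone (median 0.41, camera adjusted p = 0.252, but 0.0344 with loess and 0.0319 with Cy3 alone). hutU rose by 2.15 ± 0.35. Of the 20 largest changes under any name, 15 were genes with a locus tag only.

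Falls outside the β-lactam clusters covered 23 of 40 ribosomal protein genes with rplQ at -1.81 ± 0.26 (28 adjusted over the list alone), 12 of 33 tRNA synthetase and translation factor genes (13), 18 of 24 NADH dehydrogenase genes with nuoJ1 at -1.24 ± 0.27 (21), 5 of 6 cytochrome genes with ccsA at -2.44 ± 0.32 and qcrC at -1.94 ± 0.29 (5), and 5 of 6 citric acid cycle genes with icdA at -2.15 ± 0.31 and gltA at -2.04 ± 0.32 (5). Rises in these and the next lists, named after their values were seen apart from fusA1, were fusA1 (3.25 ± 0.30) and tuf1 (0.92 ± 0.24, but -0.36 with loess and -0.13 with Cy3 alone) among the translation factors, citA (1.40 ± 0.26), guaB1 (2.01 ± 0.26) of nucleotide synthesis and mreB1 (1.16 ± 0.23) of cell division. Of 23 amino acid synthesis genes 12 fell, with ilvH at -3.24 ± 0.29 (13 adjusted over the list alone), of 14 arginine and urea genes 7 (7), of 22 nucleotide synthesis genes 10 (10), of 19 cell division and peptidoglycan genes 10 (11) and of 6 ectoine synthesis genes 5, with ectB1 at -1.77 ± 0.24 (5).

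By camera, 14 of 37 lists were shifted, 2 up and 12 down, and 0 with an estimated correlation. Median log2 changes were -2.37 for the clavulanic acid cluster (adjusted p = 2.16e-10), -2.48 for the cephamycin C cluster (2.16e-10), -0.99 for ribosomal proteins (6.34e-08, but 0.18 with loess), -0.47 for tRNA synthetases and translation factors (0.00142, but 0.16 with loess), -1.10 for NADH dehydrogenase (4.60e-07, but 0.00 with loess), -2.17 for cytochromes (6.00e-04, but -0.04 and 0 falls with loess) and -1.91 for the citric acid cycle (0.0137, but -0.11 and 0 falls with loess). They were -1.48 for arginine and urea metabolism (4.83e-04), -1.17 for amino acid synthesis (6.22e-06), -0.83 for cell division and peptidoglycan (2.14e-04), -0.77 for nucleotide synthesis (1.65e-05), -1.39 for ectoine synthesis (0.00113), 2.15 for inositol use (0.00108) and 2.94 for branched-chain keto acid dehydrogenase (8.34e-04). With an estimated correlation the adjusted p was 0.650 for tRNA synthetases and translation factors and 0.559 for the other 13. On slide 2 the medians were -2.15, -2.36, -0.78, -0.35, -0.77, -1.88, -1.57, -1.87, -0.76, -0.66, -0.82, -1.26, 2.42 and 3.34, in the order given. With loess the ribosomal protein, tRNA synthetase, NADH dehydrogenase, cytochrome and citric acid cycle lists were not shifted, with scale normalization the citric acid cycle and tRNA synthetases were not, and with Cy3 alone the tRNA synthetases were not. Loess reduced the medians to -0.66 and -0.61 for the β-lactam clusters, with 5 and 8 falls, -0.23 for amino acid synthesis, -0.05 for cell division and peptidoglycan, -0.04 for nucleotide synthesis and -0.46 for ectoine synthesis, which were still shifted. Of 10000 random lists of like brightness, 293 had a median as low as that of ribosomal proteins, 1490 as that of tRNA synthetases and translation factors, 278 for nucleotide synthesis, 130 for cell division and peptidoglycan, and at most 39 for the other lists shifted downwards.

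**Figure D4:**
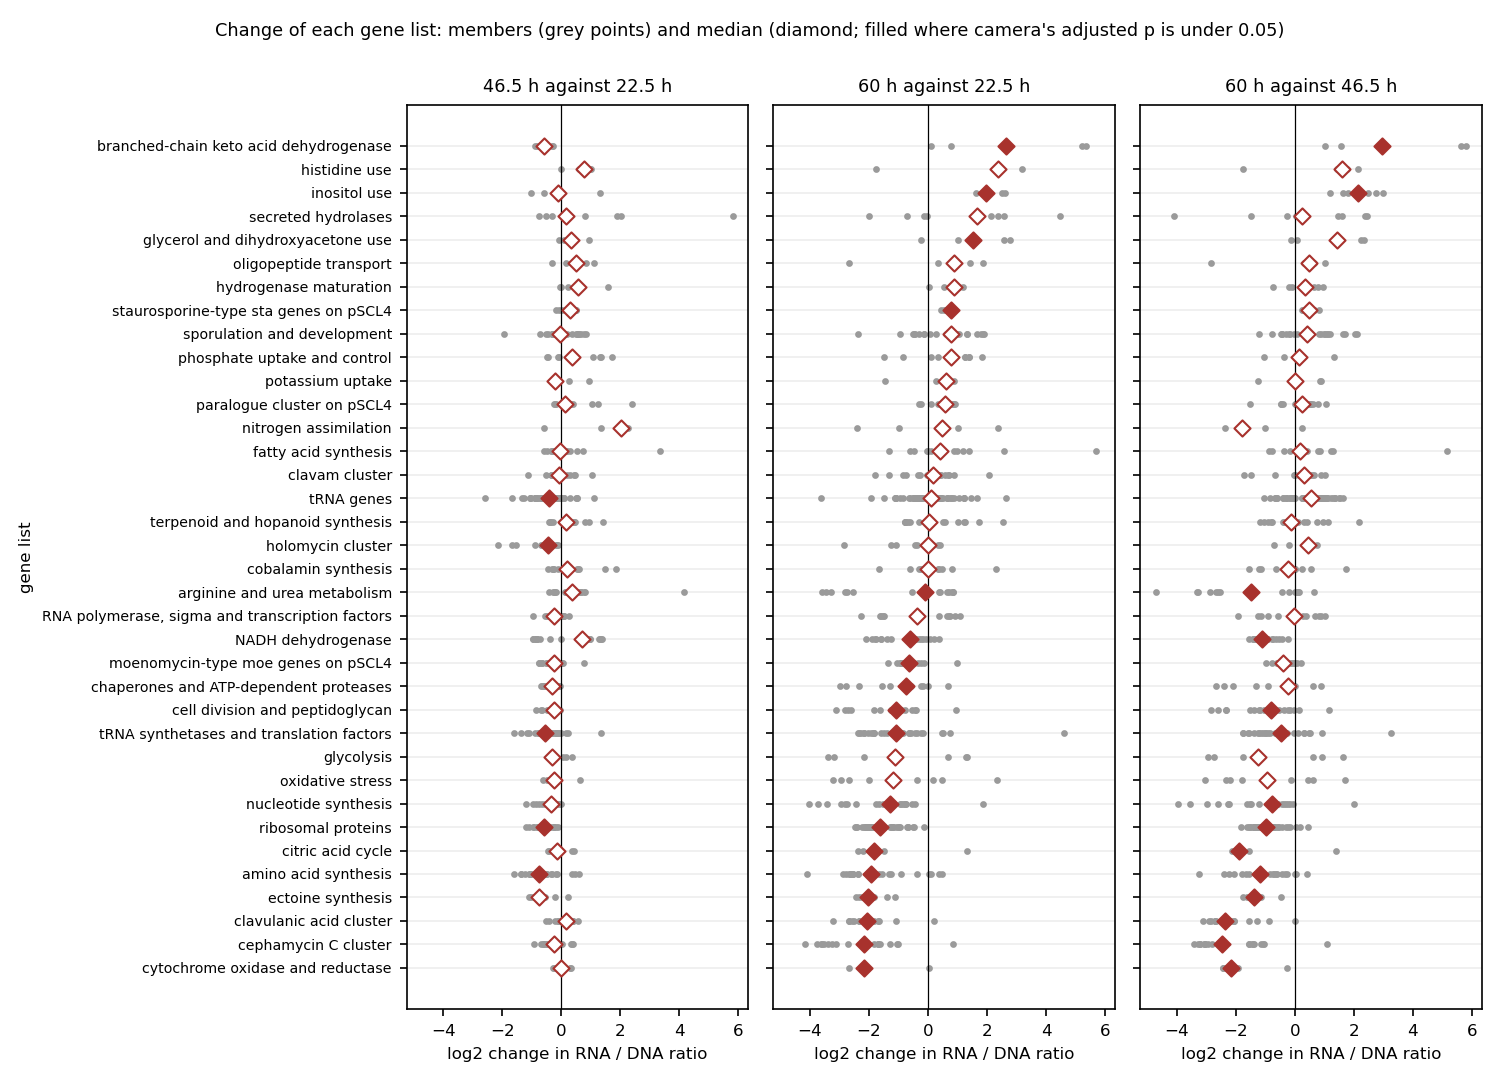
Log2 change of each list member (grey points) and list median (diamonds, filled where the list was shifted) for the tested gene lists in the 3 comparisons, without the list of all pSCL4 genes. Clavulanic acid and cephamycin C cluster medians were 0.16 and -0.25 at 46.5 h against 22.5 h and -2.08 and -2.15 at 60 h against 22.5 h, while the falls of ribosomal proteins and NADH dehydrogenase at 60 h against 46.5 h became medians of 0.18 and 0.00 with loess within each array.

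In all, 2932 of 7533 genes changed between 46.5 h and 60 h, 1750 up and 1182 down, with a median log2 change of all genes of 0.15. Changes followed brightness here too. The dimmest of 10 brightness groups had a median change of 0.91, with 511 rises and 0 falls, and the next 229 rises and 7 falls. As in the comparison with 22.5 h, the rises of the dimmest group are not shown to be rises of RNA. The brightest group had a median of -0.45, with 117 rises and 287 falls. The count was 1831 with loess, 3612 with slide as a fixed term, 4630 on slide 2 alone, and 882 and 1049 without 60 h replicate 1 and replicate 2. Over all 3 times, limma's F-test found 3594 of 7533 genes changed at any time, 2116 with loess, 5859 on slide 2 alone, and 5478, 1383 and 1590 without 46.5 h replicate 1, 60 h replicate 1 and 60 h replicate 2. In the authors' value table each of these 4 counts was 0 by limma, with 23, 13, 6 and 8 genes at an unadjusted p under 0.05 in the order 46.5 h against 22.5 h, 60 h against 22.5 h, 60 h against 46.5 h and any time.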

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

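In this part, the tests of the value-table columns, of the slides, of the replicate numbers, of ribosomal proteins at 60 h against 46.5 h and of the brighter pSCL4 genes were chosen after the results were seen.

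Tiling probes without a gene name entered no comparison of genes. Of the 3249, 768 (23.6%) were brighter in Cy3 than each of the 77 negative control spots on all 6 arrays, against 4677 of 9349 gene-designed probes. The highest negative control was 365 at 60 h replicate 1 and between 102 and 165 on the other arrays, so both counts depend largely on that array. The signal of these 768 probes lay outside the data compared between times and above the level of the negative controls, and no explanation of it was tested. Tested as probes between times by limma, 0 changed at 46.5 h against 22.5 h, 42 rose and 121 fell at 60 h against 22.5 h, and 39 rose and 81 fell at 60 h against 46.5 h.

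At 60 h against 22.5 h dim genes rose and bright genes fell, and Cy3 had a narrower range at 60 h (SD of log2 signal 1.88 and 1.82, against 2.26 and 2.17 at 22.5 h). As the whole cause of the cluster falls this trend is argued against: the medians of -2.08 (clavulanic acid) and -2.15 (cephamycin C) compare with -0.44 and -0.33 for genes of like brightness, and at most 4 of 10000 random lists of like brightness were as low. For ribosomal proteins at 60 h against 22.5 h, 11 of 10000 lists were as low (-1.61 against -0.55), under the bound set before the test. At 60 h against 46.5 h genes of like brightness had a median of -0.38 against -0.99, and 293 of 10000 lists were as low. The draws treat genes as independent, but the estimated correlation between genes was 0.498 for ribosomal proteins and 0.647 and 0.775 for the clusters. The counts therefore overstate how rare such lists are. Loess, which fits a curve to brightness and so removes changes that follow it, took the ribosomal median to 0.00 at 60 h against 22.5 h and its falls from 32 to 0. The cluster medians stayed at -0.56 and -0.59 with loess. For ribosomal proteins the trend stays open as a cause of part or all of the fall in both comparisons. For pSCL4 the median of 0.50 exceeded that of chromosomal genes of like brightness by 0.0734 (17 of 10000 draws as high). This was within the bound set before the test, so the trend may explain the rise of the pSCL4 genes as a whole. In a split chosen after that result, the dimmer 5 of 10 brightness groups had 0.55 against 0.59. The 541 genes in the brighter 5 had 0.23 against -0.28, a difference of 0.506 that 0 of 10000 draws reached. For these brighter genes the trend is argued against as the whole cause, but only with the main scaling, since the split was not repeated with others. With scale normalization the median of all pSCL4 genes was 0.15, against 0.10 for all genes tested. Weaker Cy3 labelling of an array did not give such a trend in the 46.5 h pair (dimmest minus brightest group -0.168 in the dimmer array). Both arrays of that pair had higher Cy3 medians (720 and 1144) than the 60 h arrays (372 and 313), and they were on different slides. The pair therefore cannot show what a weaker signal does at 60 h, and this cause stays open. A change in the RNA population with culture time, which the design names, also stays open and was not tested. Median Cy3 of gene spots was lower at 60 h than at 22.5 h (608 and 620). Negative control medians stayed between 62.3 and 91.3 on all arrays. Genes near the control level can therefore read as rises once each array is centred on its median, whether or not their RNA rose. How many of the called rises this covers was not tested.

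In the authors' value table limma found 0 genes changed in each comparison, with 23, 13 and 6 at an unadjusted p under 0.05. The authors' normalization alone is argued against as the cause, because 2 columns correlated best with their own scanner file and the other 4 with that of another array (best r from 0.981 to 0.994, own r as low as 0.828). A candidate explanation is that these 4 columns carry the labels of other arrays: replicates as labelled correlated at 0.871, 0.836 and 0.872 in the table and at 0.972, 0.936 and 0.982 in the scanner files. In the order of the table's columns, the best-matching scanner files run in time order with replicate 1 before replicate 2, while the column names do not. Whether the table or the scanner files carry the right labels cannot be read from these correlations alone, although scanner-file replicates correlating more closely is consistent with the scanner files being right.

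The 46.5 h replicates correlated less than those of the other times. A slide difference acting alike at both times is argued against as the whole cause by the pattern itself, since the 22.5 h pair spans the same slides and the SD of the replicate difference at 46.5 h was 1.57 times that at 22.5 h (0.736 against 0.468). This ratio restates the pattern and is no separate test of it, and a slide difference acting on the 46.5 h pair alone stays open. Something shared by arrays of one replicate number may contribute: replicate 2 minus replicate 1 correlated across genes between 46.5 h and 60 h at 0.426, and between 22.5 h and these times at 0.448 and 0.401, but the labels do not say what a number shares. That 46.5 h replicate 2 was taken at a state closer to 60 h stays open, since its difference from replicate 1 correlated with the 60 h minus 22.5 h change at 0.179, between the bounds set before the test.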

How the results depend on the processing

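In this part, the settings chosen after the results were seen were gene-designed probes alone and slide 2 alone.

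Loess within each array gave 160, 2151, 1831 and 2116 genes changed, against 560 (46.5 h against 22.5 h), 3521 (60 h against 22.5 h), 2932 (60 h against 46.5 h) and 3594 (any time), of which 147, 1702 and 1300 were shared in the 3 comparisons. It gave 2 and 12 lists shifted against 5 and 19 in the first 2 comparisons, and ccaR changed sign (0.063 at 60 h against 22.5 h and 0.20 at 60 h against 46.5 h, neither past the test), as did tuf1 at 60 h against 46.5 h (-0.36, and -0.13 with Cy3 alone, neither past the test; the cause was not tested). Loess fits a curve to brightness and so removes changes that follow it; how much of these differences that makes was not tested. The authors' value table as labelled gave 0 genes for each count and 10, 11 and 4 lists, and its columns are weighed above.

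For 46.5 h against 22.5 h, the replicate block gave 1198 genes, slide as a fixed term 1357 (all 560 shared), the 2 times alone 351, and Cy3 alone 9 lists; for these the cause was not tested. Slide 2 alone gave 2822 genes there, 4630 at 60 h against 46.5 h and 5859 at any time, with 1 residual degree of freedom, from the 60 h pair alone, and the cause was not tested. With an estimated correlation, 0, 0 and 0 lists were shifted against 5, 19 and 14.

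For oppA2 (-0.79) the value was -0.24 with loess, -1.62 with processed signals, -0.20 in the value table and -2.66 with gene-designed probes alone, which leave out its 21 tiling probes. The value-table columns were not centred (medians from 0.24 to 0.60), so that value is on another zero, and the rest of its difference was not tested. For loess and processed signals the cause was not tested. Without background correction it was -0.71.

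Leaving out 1 array gave 287 to 2350, 1700 to 4867, 882 to 3591 and 1383 to 5478 genes and 4 to 9, 17 to 19 and 14 to 18 lists; a lone array was assumed to vary like the other groups. The other settings kept each count within 1.5 times: 477 to 591, 3240 to 4859, 2235 to 3698 and 3236 to 4775 genes. The split of rises and falls moved by over 10 percentage points in 1 gene count, 60 h against 46.5 h, where it was 1300 up and 531 down with loess against 1750 and 1182. For lists at 46.5 h against 22.5 h (0 up and 5 down) it was 1 and 1 with loess, 3 and 6 with Cy3 alone, 1 and 6 with processed signals, 4 and 6 in the value table, 1 and 5 with the 2 times alone and on slide 2 alone, and 4 and 5 without 46.5 h replicate 1, with 1 list up without 22.5 h replicate 2, 46.5 h replicate 2 or either 60 h array. At 60 h against 22.5 h (5 and 14) it was 6 and 10 with scale normalization, 5 and 6 in the value table, 2 and 13 with the brightest probe and 2 and 15 on slide 2 alone. At 60 h against 46.5 h (2 and 12) it was 4 and 9 with loess, 5 and 11 with Cy3 alone and 2 and 2 in the value table.

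Of the 154 single-gene changes printed, 92 kept direction and side of the threshold with loess, 58 no longer passed and none newly passed. Of 924 values without 1 array, 836 did so, 85 no longer passed and 1 newly passed. On slide 2 alone 153 did so and 1 newly passed, which says little about stability, since 22.5 h and 46.5 h have 1 array each there and the spread comes from the 60 h pair alone. Of 2156 under all other settings 2092 did so, 55 no longer passed and 2 newly passed. The remaining values, other than those of ccaR and tuf1, belong to SCLAV_4184, which passed in neither comparison printed. Signal over background removed few genes from the tests: a filter on all 6 arrays gave 560, 3516 and 2917 genes. The flag behind this filter was set on at least 99.8% of spots for genes or tiles on each array. Of gene-designed probes 50.03% were brighter than every negative control on all 6 arrays. This share depends largely on 60 h replicate 1, where the highest control was 365 and the median gene spot 372. On the other arrays the highest control was between 102 and 165, so the share does not give the part of probes at control level. The filter therefore cannot show how far genes near the level of the negative controls contribute to the calls.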

Other observations

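In this part, the comparison of tiling with gene-designed probes was chosen after the results were seen, and the list tests were not.

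At 60 h against 22.5 h the following lists were not shifted, apart from the alternatives given. The clavam cluster had 3 rises and 4 falls of 15 genes (median 0.17, camera adjusted p = 0.932), and its median was -0.02 with loess and -0.03 with Cy3 alone. The paralogue cluster on pSCL4 had 2 rises of 16 (0.58, 0.150), or 0 adjusted over the list alone. The holomycin cluster had 2 falls of 12 (0.02, 0.308), but was shifted downwards with loess (median -0.42, 4 falls, adjusted p = 0.00164), Cy3 alone (-0.54, 6 falls, 0.0150) and slide 2 alone (-0.38, 5 falls, 0.0388), and its median was -0.27 with quantile and -0.31 with scale normalization. Terpenoid and hopanoid genes had 5 rises and 1 fall of 18 (0.04, 0.863; 5 and 6 with a replicate block), with hopC, of hopanoid synthesis, at 2.54 ± 0.29 and geoA, of geosmin synthesis, at 1.74 ± 0.28. Phosphate genes had 5 rises and 2 falls of 11 (0.77, 0.236), with the phosphate transporter gene pstC at 1.84 ± 0.39, or 7 rises adjusted over the list alone, and with loess the list was shifted upwards (6 rises, 0 falls, adjusted p = 0.0474). Fatty acid synthesis had 5 rises and 1 fall of 14 (0.41, 0.242), and was shifted upwards with Cy3 alone (median 0.80, adjusted p = 0.0281). Hydrogenase maturation had 3 rises of 8 (0.88, 0.150), but 0 with loess (median 0.48) and 5 with a replicate block, and tRNA genes 9 rises and 5 falls of 53 (0.10, 0.856, with a median of 0.00 with scale normalization). Nitrogen assimilation had 1 fall of 5, the glutamate synthase gene gltD (-2.42 ± 0.28; median 0.46, 0.831, but -0.66 and 2 falls with slide as a fixed term), and oligopeptide transport 2 rises and 1 fall of 4 (0.89, 0.820). Cobalamin synthesis had 1 rise, of cbiM (2.32 ± 0.29), and 1 fall of 11 (-0.01, 0.863, and 0.12 with scale normalization), and potassium uptake 1 fall of 5 (0.63, 0.831, and -0.12 with loess). Of the lists too small to test, all 3 ATP synthase genes fell, with atpA2 at -3.42 ± 0.27, and 1 of 2 iron uptake genes rose.

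Median, mean and test differed in sign in some lists that were not shifted. At 46.5 h against 22.5 h these were the clavam cluster, cytochromes, the citric acid cycle, sporulation and development, fatty acid synthesis, the list of all pSCL4 genes and potassium uptake. At 60 h against 22.5 h they were the clavam cluster, the holomycin cluster, nitrogen assimilation, tRNA genes and cobalamin synthesis, and at 60 h against 46.5 h oligopeptide transport and potassium uptake.

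Genes with both probe kinds, 175 in number, read 0.59 (log2) higher by tiling than by gene-designed probes in the median, and 52 had means over 1 apart. The SD of probes within a gene had a median of 0.77 for tiling and 0.54 for gene-designed probes. The mean log2 ratio of all 24 oppA2 probes was -1.07 and -0.81 at 22.5 h, -0.98 and -0.70 at 46.5 h, and -0.78 and -0.40 at 60 h. The log2 ratios of 46.5 h and 22.5 h replicate 1, both on slide 1, correlated at 0.946 across genes, and the 46.5 h replicates at 0.943.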
